A study of Mus musculus with 8 samples.

How the data were processed

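Gene expression was measured by RNA sequencing in 8 libraries labelled as the mouse cell line C2C12. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with an Illumina TruSeq RNA kit. The samples fall into 4 groups by their labels: a DMSO library (n = 1) and a library of cells given ginseng berries concentrate (GBC, n = 1) in one table, and 3 DMSO libraries and 3 ginsenoside Re libraries in another table. The submitters' processing notes name STAR and RSEM, without versions, and the genome builds GRCh38 and GRCm39. Their settings, and which build was used for which step, are not given in the sources used here.

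The values as deposited are log2(TPM + 1) per Ensembl gene: the authors divided estimated reads by gene length, scaled each library and took the log2, as far as the file shows. Back-transformed, the deposited values were multiples of 0.01 TPM within 2.0e-04. TPM keeps no read depth, so the depth of each library is unknown, no count model was used, and no counting interval can be given. The TPM of the listed genes sum to less than 1000000 in each library, so some features of the authors' annotation are not among the rows used here. The tables list 52139 and 52338 genes, of which 52139 are in both. The 2 tables were treated as normalised separately, so tests were made within a table, and levels set across tables are descriptions.

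For gene length and biotype, 51884 and 52081 of the Ensembl IDs matched the GENCODE M21 annotation. That annotation is on GRCm38, another build than the GRCm39 of the notes, so no coordinates were taken from it. Length is the union of a gene's exons. Gene symbols are those of the deposited tables.

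Re was compared with DMSO by limma 3.58.1 in R 4.3.3, with a moderated two-sided test (lmFit and eBayes with trend) on log2(TPM + 1), a pseudocount of 1, over the genes with a mean of at least 1 TPM in the 6 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. Differences are on the log2(TPM + 1) scale, which understates the change of low genes. The 36 gene lists were tested with camera at a preset correlation of 0.01, where at least 5 members passed the filter, with camera at an estimated correlation and fry beside it. Camera compares a list with other genes, while fry asks whether its genes move one way at all. On simulated libraries with the spread of the real ones, the limma step recovered 0.5% of genes changed by 1.5-fold, 65.1% of those changed by 2-fold and 90.2% of those changed by 4-fold with 200 of 11967 genes changed in each of 5 simulations, so small changes of single genes would be missed. The list step recovered 20 of 20 simulated lists of 30 genes raised by 0.3 and called 0 of 20 unchanged lists. The simulated libraries had no correlation between genes. The rise of 0.3 was larger than the leads of the called lists over all genes, which were 0.041 to 0.05. Recovery of lists at that size was not simulated.

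The GBC and DMSO libraries are 1 per group, so no test was made. Genes with a mean of at least 5 TPM and a difference of at least 1 were counted, and the same count was made for each pair of libraries of 1 group in the Re table. Gene lists with at least 5 members at a mean of at least 1 TPM were described by the median difference and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. On shuffled data the percentile placed 20 of 20 lists of 30 genes raised by 0.5 above the central 95% of random lists, and 2 of 20 unchanged lists fell outside it. The shuffled data had no correlation between genes. The GBC and Re differences were compared across genes by Pearson's r and Spearman's rho. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and the figures matplotlib 3.10.9.

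Genes were named by a rule fixed before the data were examined, as were the tests and gene lists. For Re the rule takes the genes with the largest changes past the threshold, and, where none passes, the 10 with the smallest p. For GBC it takes the 12 largest differences either way at a mean of at least 5 TPM. From each list described it takes up to 4 members, with the smallest p for Re and the largest difference for GBC. Predicted and unnamed gene models and pseudogenes were left out of the naming, not of the counts. A further 10 genes were fixed by name. Genes named for their levels in both tables, such as Des and Thy1, and the values of Rps16 in the Re table were chosen after they were seen. Alternatives fixed then too were other pseudocounts of 0.1 and 0.5, other filters on TPM, median-of-ratios scaling, quantile normalization, leaving out mitochondrially encoded genes, limma without trend or with robust variances, a replicate block, and leaving out each library in turn. Where mitochondrially encoded genes were left out, those of mitochondrial rRNA included, the other genes of each library were rescaled to a sum of 1000000 TPM. The count and the comparison of GBC with Re over protein-coding genes alone, the count with the median shift taken out, corrections for gene length that take out the median shift too, lists matched on length, scaling in the count of genes whose Re values all lie on one side, left-out libraries in the comparison of GBC with Re, and combinations of scaling with the block or the estimated correlation were added after the data were seen. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.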

Results

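The data are RNA sequencing profiles of cells labelled C2C12, an immortalised mouse myoblast line that can fuse into contractile myotubes. The study asked what ginseng berries concentrate (GBC) and ginsenoside Re, a saponin of ginseng, do to gene expression in such cells, with DMSO, a solvent, as the control. For GBC there was 1 treated and 1 DMSO library, and for Re there were 3 treated and 3 DMSO libraries. Doses and treatment times were not given in the labels. The labels call the cells myoblasts, while the text of the series speaks of myocytes. Values were TPM, whose depth is unknown. The TPM of the listed genes summed to 403442 in the DMSO library and 479938 in the GBC library of the first table. In the Re table the sums were 716589, 642180 and 700100 in the DMSO libraries and 704657, 707385 and 743269 in the Re libraries. The 10 most abundant genes held 32.5% and 32.3% of that TPM in the DMSO and GBC libraries of the pair and 20.5% to 23.7% in the libraries of the Re table.

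No single gene passed the threshold between the Re and DMSO libraries: 0 of 11967 genes had an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.687. At an unadjusted p under 0.05 there were 745 genes, where chance alone gives 598, and limma without trend and robust limma called 0 genes too. The gene with the smallest p was Tpmt (ENSMUSG00000021376), which encodes thiopurine methyltransferase, at 3.96 ± 0.405 TPM in DMSO and 7.58 ± 0.922 TPM in Re (SD, n = 3), a log2 difference of 0.79 with a 95% confidence interval of 0.47 to 1.11. Acadsb, an acyl-CoA dehydrogenase of branched-chain amino acid breakdown, was at 15.8 ± 0.746 TPM in DMSO and 24.7 ± 3.34 TPM in Re, a difference of 0.60. Sirt4, a mitochondrial sirtuin, was at 6.59 ± 0.732 TPM and 11.4 ± 2.09 TPM, a difference of 0.70. Eif1ax, a translation initiation factor, was at 42.4 ± 6.09 TPM and 62.2 ± 3.94 TPM, a difference of 0.55. The other genes of this rank were Spindoc, Kpna2rt, Rsrp1, Pyroxd1, Tmx3 and Myo9a, with differences of 0.50, 0.51, 0.42, 0.59, 0.37 and 0.62. In each of these 10 genes all 3 Re values lay above all 3 DMSO values, and each had an adjusted p of 0.687 in limma. Such separation, in either direction, was seen in 1791 genes, 1639 higher and 152 lower, which is 15% of those tested, where chance gives 10%. After median-of-ratios scaling it was seen in 1215 genes, 10.2%, with 632 higher and 583 lower.

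Differences lay mostly on one side in the deposited values: the median over all genes was 0.105 higher in Re, and 676 of the 745 genes were higher, which is 90.7%. The share higher was 76.5% without DMSO replicate 2, where the median was 0.054, 70.2% without Re replicate 3, and 85.4% to 93.4% without any of the other 4 libraries. With mitochondrially encoded genes left out and each library rescaled to a sum of 1000000 TPM it was 62.4%, with a median of 0.022. The removal and the rescaling cannot be told apart here, since the deposited sums differed between libraries. After median-of-ratios scaling the median was 0.001 and 256 of 563 genes were higher, and the differences of the 39 genes named by rule for Re were 0.09 to 0.11 lower than those given here. Leaving out 1 library at a time called 4 genes without DMSO replicate 1, 6 without DMSO replicate 2, 3 without Re replicate 1, 1 without Re replicate 2, 7 without Re replicate 3 and 0 without DMSO replicate 3. The number at an unadjusted p under 0.05 was 1657 without DMSO replicate 1 and 424 to 583 without any of the other 5 libraries. Among the genes called so, chosen after their values were seen, were the mitochondrial leucyl-tRNA synthetase gene Lars2, at -5.80 without DMSO replicate 1, and mt-Co2, a subunit of complex IV, without Re replicate 2. The gene mt-Co2 was listed at 0 in all 3 DMSO libraries and at 50.5 ± 56.6 TPM in Re (SD, n = 3), with 0 in Re replicate 2. The 95% confidence interval of a gene reached 0.314 to either side of its difference at the median over genes.

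Of 31 gene lists tested, 3 were called higher in Re relative to other genes by camera with its preset correlation. Genes of ribosomal proteins had a median difference of 0.148 and an adjusted p of 0.00714, and of 0.97 with an estimated correlation, with 77 of 79 measured members higher. Their lead over the median of all genes was 0.043. Rplp2, Rpl7 and Rps3, parts of the ribosome, differed by 0.27, 0.23 and 0.25. Targets of ATF4 and of the unfolded protein response had a median of 0.146 and an adjusted p of 0.0137, and of 0.97 with an estimated correlation, with 40 of 41 members higher and a lead of 0.041. Pck2, a mitochondrial enzyme that makes phosphoenolpyruvate, was at 25.3 ± 1.81 TPM in DMSO and 33.1 ± 2.03 TPM in Re (SD, n = 3), a difference of 0.38, and Trib3, Asns and Atf3 differed by 0.48, 0.24 and 0.37. Nuclear genes of oxidative phosphorylation had a median of 0.155 and an adjusted p of 0.0137, and of 0.97 with an estimated correlation, with 73 of 75 members higher and a lead of 0.05. Ndufs5 and Ndufa1, subunits of complex I, and Uqcrh, of complex III, differed by 0.29, 0.34 and 0.25. Most members were higher in some lists not called too, such as 22 of 24 p53 targets and 40 of 45 cell cycle genes. Among myogenic regulators and fusion genes 8 of 15 were higher. No member of any list passed alone, with 0 genes past the threshold over all genes and 0 adjusted over the list alone.

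These 3 calls were not kept with an estimated correlation, where each had an adjusted p = 0.97. Another question, whether a list moves one way at all without regard to other genes, was asked with fry, where each of the 3 had an adjusted p of 0.384. After median-of-ratios scaling the adjusted p from limma's camera was 0.231 for ribosomal proteins, 0.231 for ATF4 targets and 0.273 for oxidative phosphorylation, and the medians were 0.034, 0.033 and 0.043. Each call also depended on single libraries. Ribosomal proteins had an adjusted p of 0.133 without DMSO replicate 2, 0.0615 without DMSO replicate 3 and 0.211 without Re replicate 2. ATF4 targets had 0.0502 without DMSO replicate 1, 0.0615 without DMSO replicate 3, 0.211 without Re replicate 2 and 0.167 without Re replicate 3. Oxidative phosphorylation had 0.444 without DMSO replicate 2, 0.0615 without DMSO replicate 3, 0.325 without Re replicate 1 and 0.245 without Re replicate 2. Left-out libraries also moved the number of lists called, from 3 to 2 without DMSO replicate 1 or Re replicate 1, to 4 without Re replicate 3, of which 2 were lower, and to 0 without DMSO replicate 3 or Re replicate 2. Without DMSO replicate 2 there were 3 calls, 1 higher and 2 lower.

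**Figure D1:**
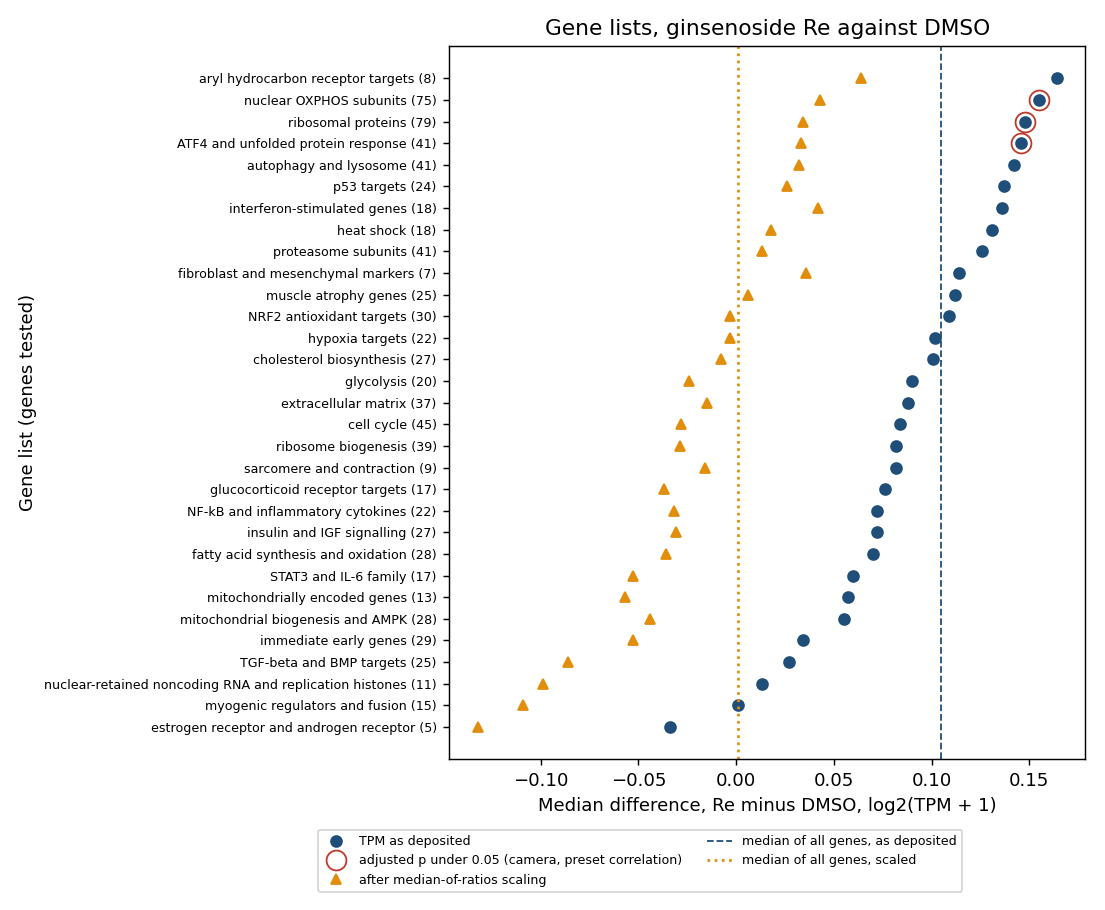
Median difference between Re and DMSO libraries (log2(TPM + 1), horizontal axis) for each of 31 gene lists, with the number of genes tested in brackets. Circles are the deposited values, triangles the values after median-of-ratios scaling, and ringed circles the 3 lists called by camera with its preset correlation; lines mark the medians of all genes, 0.105 and 0.001.

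Muscle genes showed no called difference. The 15 measured myogenic regulators and fusion genes had a median difference of 0.001, with 8 higher and 7 lower, and an adjusted p of 0.273 in limma's camera test. That median lay 0.105 below that of all genes and was -0.109 after median-of-ratios scaling. Id1, an inhibitor of MyoD, differed by 0.23 and Musk, a receptor kinase of the neuromuscular junction, by 0.24, or by 0.12 and 0.14 after scaling. Id1 differed by 0.14 without DMSO replicate 2. Mef2d, a transcription factor of muscle differentiation, was at 17.9 ± 0.829 TPM in DMSO and 15.98 ± 1.38 TPM in Re (SD, n = 3). The 9 sarcomere genes had a median of 0.082, a mean of 0.034 and an adjusted p of 0.219, and camera placed them below other genes. For the muscle atrophy list the median was 0.112, within 0.007 of all genes, with an adjusted p of 0.515 over 25 genes; Ctsl, a lysosomal protease, differed by 0.25. Among genes of mitochondrial biogenesis and AMPK, with an adjusted p of 0.785 over 28 genes, Mfn1, which fuses mitochondrial outer membranes, differed by 0.75, Sirt3 by 0.48, and Tfam, a factor of mitochondrial DNA, by 0.47. The median of that list lay 0.05 below that of all genes, while camera placed the list above other genes. The cell cycle, glycolysis, hypoxia and extracellular matrix lists also had medians below that of all genes and a test direction upward, and the list of estrogen and androgen receptor genes had a median of -0.034 and a mean of 0.001. Over the 28 lists not called, the adjusted p from limma's camera ran from 0.219 to 0.937.

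Of the genes fixed by name, Fst, which encodes the myostatin antagonist follistatin, was at 9.35 ± 0.679 TPM in DMSO and 11.5 ± 1.02 TPM in Re (SD, n = 3), a difference of 0.27 with a 95% confidence interval of 0.01 to 0.53 that does not pass adjustment (adjusted p 0.687 in limma). Fbxo32, the atrophy ubiquitin ligase atrogin-1, was at 4.76 ± 0.136 and 5.42 ± 0.153 TPM, a difference of 0.16 with an interval of -0.11 to 0.42. Myod1 was at 12.2 ± 0.326 and 11.6 ± 1.87 TPM, a difference of -0.08 with an interval of -0.37 to 0.22. Actb and Gapdh differed by -0.02 and -0.01. After median-of-ratios scaling Fst differed by 0.16, Fbxo32 by 0.06, Myod1 by -0.18, and Actb and Gapdh by -0.13 each. Trim63, Myog, Mstn, Ppargc1a and Igf1 were under 1 TPM in each of the 6 libraries and were not tested.

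In the GBC pair the GBC library had higher values than the DMSO library for most genes, by 0.307 at the median of 6639 genes with a mean of at least 5 TPM. The listed TPM also summed higher in the GBC library, to 479938 against 403442, so much of this shift goes with the sums. A rescaling to equal sums with all genes kept was not made. Past the size rule there were 346 genes, 330 higher and 16 lower, so that 95.4% were higher. After median-of-ratios scaling there were 141, of which 83.0% were higher. These are 5.21% of the genes as deposited and 2.12% after scaling. With mitochondrially encoded genes left out and both libraries rescaled to the same sum, 231 genes were past the rule. Of these 91.3% were higher, and the median difference was 0.119. Pairs of DMSO libraries of the Re table had 0.92% to 1.41% of 9061 to 9205 genes past the rule as deposited and 0.96% to 1.41% after scaling. Pairs of Re libraries had 1.02% to 1.42% of 9288 to 9378 genes as deposited and 1.01% to 1.35% after scaling. With 1 library per group the differences have no replicate check, and some muscle identity genes such as Myod1 were listed at or near 0 in both libraries. Differences of single genes in the pair are given below with the median shift of 0.307 left in. With it taken out, rises are smaller and falls larger, as for Osgep at -0.886 in place of -0.579.

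Of the 12 largest positive and 12 largest negative differences in named genes, 6 and 1 were in small nucleolar RNAs, a class that guides the modification of ribosomal RNA. Snora41, Snora65, AF357399, Mir669h and Snora69 were listed at 0 in the DMSO library and at 33.7, 30.3, 20.02, 20.02 and 12.1 TPM in the GBC library, and Snora43 at 26.5 TPM in DMSO and 0 in GBC. These genes are 125 to 132 bases long, so few reads may give such TPM, and the depth is unknown. AF357399 and the microRNA gene Mir669h had identical values. Snora28 and Snora16a were 2.89 and 2.69 higher on the log2 scale. Rps16, a protein of the small ribosomal subunit, was at 2.22 TPM in DMSO and 97.1 TPM in GBC, a difference of 4.93. In the Re table Rps16 ran from 905.2 to 1119 TPM. Whether reads of such genes are shared with pseudogene copies was not tested. Cd9, a tetraspanin of the plasma membrane, was at 2.63 and 27.0 TPM, a difference of 2.95. H3f3b, a histone H3.3 gene, was at 32.3 and 202.1 TPM, a difference of 2.61. Rhoc, a small GTPase, and Cpe, carboxypeptidase E, were 2.40 and 2.34 higher. Among the lower genes, Uqcrq, a subunit of complex III, was at 92.2 TPM in DMSO and 42.8 TPM in GBC, a difference of -1.09, and Tpt1, translationally controlled tumour protein, at 679.1 and 334.8 TPM, a difference of -1.02. The next were mt-Co3, Get4, Ddx51, Emp1, Rpp40, Cldnd1, Lrrc42, H4c12 and Osgep, with differences between -0.79 for mt-Co3 and -0.58 for Osgep. Further protein-coding genes, chosen after their values were seen, were Rrs1, Ddx3x, Trappc6b, Dnajc7, Ece1 and Txn2, which were 1.90 to 2.08 higher in the GBC library.

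Mitochondrially encoded genes were the list with the largest median, 1.298 over 13 genes, with 9 members past the size rule. Their median lay 0.978 above that of all genes with a mean of at least 1 TPM, which was 0.32, and at percentile 100 of matched random lists. The mRNA of mt-Nd4, a complex I subunit, was at 139.5 TPM in DMSO and 424.0 TPM in GBC, and mt-Nd6, mt-Co2 and mt-Nd2 were 1.57, 1.53 and 1.49 higher, while mt-Co3 was lower. Extracellular matrix genes had a median of 0.733 over 35 genes, 0.413 above all genes, at percentile 100, and 10 of them passed the size rule. Col1a1, which encodes the alpha chain of type I collagen, was at 10.9 and 46.6 TPM, a difference of 1.996, and Lamb1, Thbs2 and Nid1, of the basement membrane and matrix, were 1.34, 1.27 and 1.23 higher. Insulin and IGF signalling genes had a median of 0.534 at percentile 99.5, where Rptor, a subunit of mTORC1, was 1.16 higher. Targets of TGF-beta and BMP had a median of 0.491 at percentile 97.9, where Thbs1 was 1.16 higher. The first of these lay at percentile 91.3 among lists matched on gene length too, and the other at 97.0 after scaling, inside the central 95% of random lists.

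Nuclear genes of oxidative phosphorylation had the lowest percentile, 0.04, though not the lowest median, with a median of 0.071 over 75 genes, 0.249 below all genes. Members went both ways: Ndufs6 and Sdha were 1.34 and 1.18 higher and Uqcrq was lower. Ribosomal protein genes had a median of 0.039 over 79 genes, 0.281 below all genes, at percentile 0.26, although Rps16 and Rpl11 were 4.93 and 1.66 higher. Interferon-stimulated genes had a median of 0.062 over 15 genes at percentile 0.09, with Trim25 0.72 higher. For nuclear-retained RNAs and replication histones the median was -0.034 and the mean 0.18 over 11 genes, at percentile 0.92, with Malat1 and Neat1 1.07 and 1.15 higher and H4c8 at 625.6 TPM in DMSO and 487.8 TPM in GBC. In total 8 of 29 lists lay outside the central 95% of their random lists. Random lists were drawn without regard to correlation between genes, so lists whose genes vary together can fall outside between any 2 libraries. The percentiles were not computed for pairs of control libraries.

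**Figure D2:**
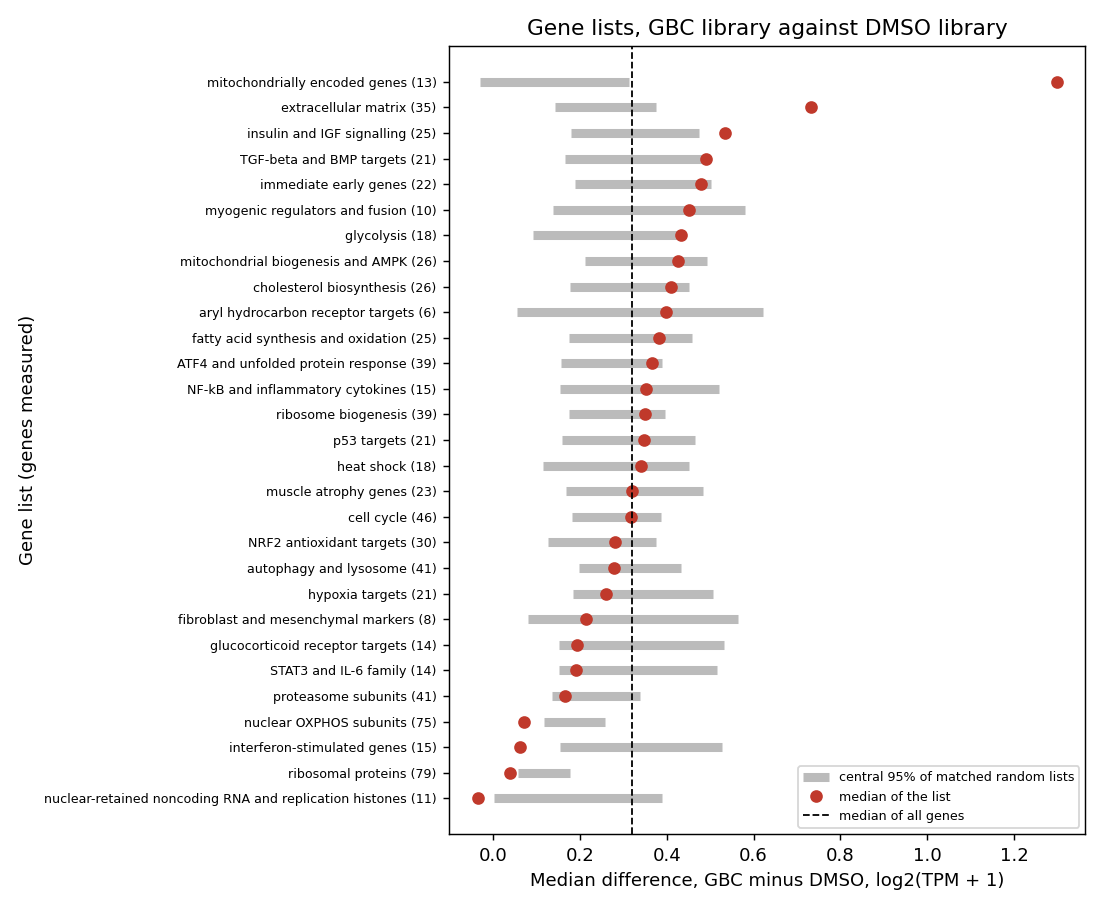
Median difference between the GBC and DMSO libraries (log2(TPM + 1), horizontal axis) for each of 29 gene lists, with the number of genes measured in brackets. Points are list medians, grey bars the central 95% of 10000 random lists matched on expression, and the dashed line the median of all genes, 0.32; there is 1 library per group. Mitochondrially encoded genes lie highest at 1.298.

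The muscle atrophy list was not set apart, with a median of 0.319 over 23 genes at percentile 57.1; Ddit4, an inhibitor of mTORC1, Cblb, Foxo3 and Trp53inp2 were 1.01, 0.83, 0.72 and 0.58 higher. NRF2 targets had a median of 0.281 over 30 genes at percentile 75.8, although Hmox1, haem oxygenase 1, was at 9.26 TPM in DMSO and 35.1 TPM in GBC. Heat shock genes had a median of 0.341 at percentile 81.7, and Hsp90ab1, Cryab and Dnaja1 were 1.52, 1.45 and 1.45 higher. The cell cycle list had a median of 0.318 over 46 genes at percentile 80.2, with 8 members past the size rule, among them Foxm1 at 1.43, Cenpf at 1.33 and Plk1 at 1.25. Actb was at 1269 and 1626 TPM and Gapdh at 456.3 and 696.9 TPM.

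Differences in the GBC pair were larger in longer genes. Among protein-coding genes with a mean of at least 5 TPM split by exon length into 5 groups of like size, the median difference was 0.15 in the shortest group and 0.52 in the longest, and Spearman's rho with exon length across 6239 genes was 0.407. Within the groups of the Re table the rho between 2 libraries ran from -0.073 to 0.275 over 6 pairs. From a DMSO to a Re library it ran from -0.179, for DMSO replicate 2 and Re replicate 2, to 0.229, for DMSO replicate 1 and Re replicate 3. Genes are not independent replicates in these values. Whether gene length bears on the lists called for Re was not tested.

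**Figure D3:**
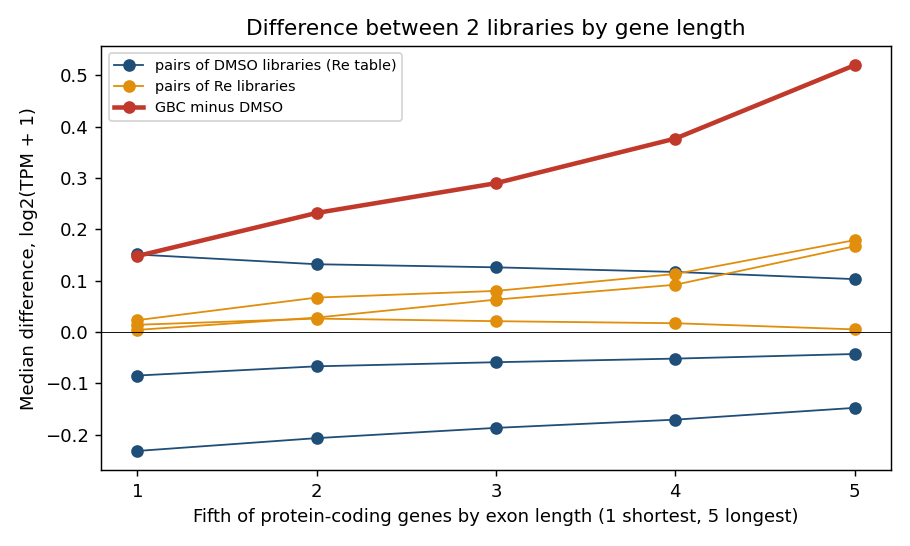
Median difference between 2 libraries (log2(TPM + 1), vertical axis) in each of 5 groups of protein-coding genes by exon length (horizontal axis). The thick line is GBC minus DMSO, which runs from 0.15 to 0.52, and the thin lines are pairs of DMSO or of Re libraries of the Re table, which run between -0.232 and 0.179.

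The GBC and Re differences had a weak negative correlation across genes. Over 10328 genes with a mean of at least 1 TPM in both tables, Pearson's r was -0.127 and Spearman's rho -0.121, and 44.9% of genes lay on the same side of both medians. Genes are not independent replicates, and the DMSO libraries of the 2 comparisons differ. The value depended on single libraries, with r = -0.044 without Re replicate 2 and -0.206 without Re replicate 3. Since Re called no gene, the GBC differences of genes called by Re could not be given.

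The levels of muscle genes address how far the cells of each library were differentiated. The tables were processed separately, so their levels are set side by side without a test. Several muscle identity genes lay lower in the GBC pair, while Mef2c of the same list was at 3.09 and 5.86 TPM in the pair and 0.33 TPM on average in the Re table. Myod1, the myoblast determination factor, was listed at 0 TPM in both libraries of the GBC pair and ran from 9.95 to 13.6 TPM in the 6 libraries of the Re table. Myf5, a related factor, was listed at 0 in the pair and at 32.4 TPM on average in the Re table, and Cdh15, M-cadherin, at 0 and 14.5 TPM. Des, the muscle intermediate filament desmin, was at 1.92 and 1.59 TPM in the DMSO and GBC libraries of the pair and at 119.8 TPM in the Re table. Acta2, smooth muscle actin, was at 6.49 and 7.94 TPM against 1445 TPM. A listed 0 need not mean that a transcript was absent, since mt-Co2 was listed at 0 in the 3 DMSO libraries of the Re table. Myog, which is switched on as myoblasts differentiate, was under 1 TPM in all 8 libraries. Some markers of mesenchymal cells lay higher in the pair: Thy1 was at 23.8 and 22.1 TPM in the pair and under 0.1 TPM in the Re table. Cd34 was at 51.5 and 49.5 TPM against 3.31 TPM, and Ly6a at 51.5 and 58.5 TPM against 13.8 TPM. Others lay lower, with Pdgfrb at 1.78 and 3.26 TPM against 15.01 TPM and Tcf4 at 3.58 and 7.92 TPM against 20.8 TPM. Actb and Gapdh lay lower in the pair as well, Actb at 1269 and 1626 TPM against 5549 TPM. Gapdh was at 456.3 and 696.9 TPM against 2332 TPM. A moderately lower level in the pair therefore need not be particular to a marker. Of the fixed genes, Fbxo32 and Fst were at 0.29 and 0.87 TPM in the DMSO library of the pair and 0.35 and 0.84 TPM in the GBC library. Markers of endothelial and of epithelial cells each summed to at most 1.9 TPM in any library, those of adipocytes to 15.9 TPM and those of macrophages and leukocytes to 14.8 TPM. Markers of osteoblasts and cartilage summed to 237.6 to 688.6 TPM, mostly Spp1 at 271.7 and 221.9 TPM in the pair and 620.9 TPM on average in the Re table. Across 11967 genes, Pearson's r was 0.769 to 0.804 between libraries of different tables and 0.962 to 0.978 within the Re table.

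**Figure D4:**
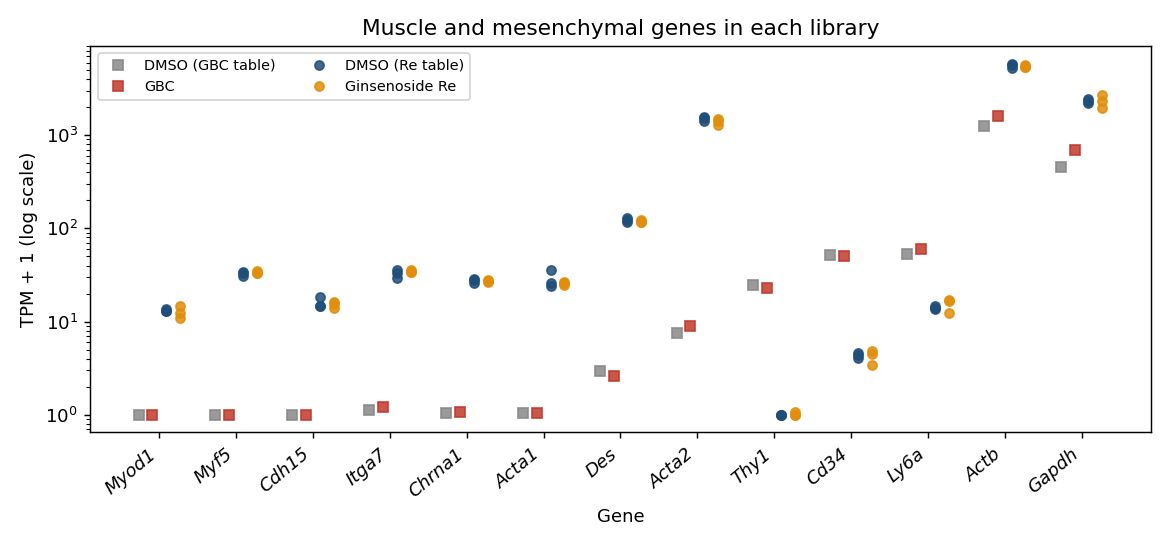
Level of muscle and mesenchymal genes (TPM + 1 on a log axis, vertical axis) in each of the 8 libraries, with squares for the GBC pair and circles for the Re table. Des lies at 1.92 and 1.59 TPM in the pair and at 119.8 TPM on average in the Re table, and Thy1 only in the pair above 1 TPM.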

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

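Alternatives added after the data were seen are those that name gene length, protein-coding genes, the median shift, a pair of settings together, the separation of genes after scaling, and the left-out libraries in the comparison of GBC with Re. The count of 0 genes called in Re was also 0 under the 10 alternatives fixed in advance that keep all 6 libraries and under scaling with the replicate block, and leaving out 1 library gave 0 to 7 genes. The number of lists called, 3 as reported, was 7 with no filter and 1 at a mean of at least 5 TPM. It was 0 with median-of-ratios scaling, quantile normalization, limma without trend, and mitochondrially encoded genes left out with the rest rescaled. It was also 0 with an estimated correlation, scaling with the estimated correlation, and scaling with the replicate block. Left-out libraries gave 0 to 4. With fry, which does not compare a list with other genes, 0 lists were called. With the replicate block 0 genes and 3 lists were called. Deviations of libraries with the same number correlated at 0.163, 0.077 and 0.017, and those with different numbers at -0.172 to 0.094. DMSO replicate 2 correlated best with Re replicate 3, at 0.094. Whether libraries with the same number are pairs cannot be told from these values. For GBC the 346 genes past the size rule became 141 after scaling, 522 at a mean of at least 1 TPM, 218 at 10 TPM, 1443 at 1.5-fold, 297 among protein-coding genes, 95 of those with the median shift taken out, and 94 with the median shift and the length trend taken out; no paired analysis was possible because each group has 1 library. The 8 lists outside the central 95% were 7 to 9 elsewhere. The correlation of -0.127 between GBC and Re was -0.08 over the 9571 protein-coding genes, -0.065 over these with the median shift and the length trend taken out (Spearman's rho -0.112, against -0.121), and ran from -0.206 to -0.044 over left-out libraries. Re differences near 0 changed sign: over left-out libraries Myod1 ran from -0.19 to 0.02, Actb from -0.07 to 0.02 and Gapdh from -0.12 to 0.1, with Gapdh at 0.02 without DMSO replicate 3, and Itga7 was at -0.01 under scaling and under scaling with the block. Over left-out libraries the mitochondrial biogenesis and AMPK list had an adjusted p of 0.707 to 0.989 in limma's camera, and its direction turned at 0.989, without Re replicate 3. For the 79 genes named for GBC, 293 values moved by less than 0.476, the spread between DMSO libraries, and 18 by more, those of small RNAs listed at 0 in DMSO or in GBC. The cause was not tested, except that higher thresholds leave fewer genes. Depth is unknown, so no limit from counting can be given.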

Other observations

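All patterns and tests in this part were chosen after the data were seen. For the 2 tests of the length trend the bounds were written after the trend was seen but before their own values. With muscle genes such as Myf5 counted, 117 genes were at 10 TPM or more in all 6 libraries of the Re table and under 0.5 TPM in both libraries of the GBC pair. The most abundant named ones were Crip1 at 373.2 TPM on average in the Re table, Rps3a3 at 337.3 TPM and the heat shock protein gene Hspb1 at 270.7 TPM. Next came Crip2 at 184.3 TPM, Nes, which encodes nestin, at 171.3 TPM, Asb5 at 135.7 TPM and the smooth muscle calponin gene Cnn1 at 129.8 TPM. Whether reads of Rps3a3 are shared with related genes was not tested. The Hox genes Hoxc10 and Hoxa9 were among them, at 26.5 and 14.3 TPM. In the other direction, Dlk1, an imprinted gene of mesenchymal progenitors, was at 63.05 and 93.1 TPM in the pair and listed at 0 in the Re table. These genes were chosen after their values were seen, and the tables were processed separately.

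Some myogenic transcripts lay near 0 in both libraries of the GBC pair, which are labelled as the same line, while the myogenic list as a whole summed to 130.9 and 172.5 TPM. Low detection across all genes is argued against: 2.16% of 6055 protein-coding genes at 10 to 100 TPM in the Re table were under 0.5 TPM in both libraries of the pair, against 5 of 10 myogenic-list genes at that level. Differentiation into myocytes is argued against by the levels of the sarcomere genes. The 43 genes of that list summed to 23.4 and 34.1 TPM in the DMSO and GBC libraries of the pair. In the Re table they summed to 1373.2 to 1651.9 TPM, most of it Acta2. Acta1 was at 0.05 TPM in both libraries of the pair, against 26.1 TPM on average in the Re table. Des was at 1.92 and 1.59 TPM against 119.8 TPM, while Mef2c lay higher in the pair. The number of genes at 5 TPM argues against it only weakly. Fewer genes reached 5 TPM in the pair in other lists too, with 27 and 28 autophagy and lysosome genes against 38 to 39, and a listed 0 need not mean absence. In both libraries of the pair 2 sarcomere-list genes reached 5 TPM, against 5 in all 6 others, and Myog was listed at 0. Cells of another expression state may account for it. In both libraries of the pair 26 genes were at 10 TPM or more while under 0.5 TPM in all 6 others. Any 2 of the 6 gave at most 4 such genes against the rest. Those 6 share a table, so the comparison cannot tell separate processing of the tables from another expression state. Whether that is another line, a changed subline, culture conditions or a wrong label stays open, as does separate processing of the tables, and no other biological explanation was tested.

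The GBC difference was larger in longer genes. Length bias between single libraries cannot be told apart from an effect of GBC, because each group has 1 library: the largest rho with length within groups of the Re table was 0.275, against 0.407 for the pair. The length trend as the whole cause of the excess of higher genes is argued against, since 94.7% of the genes past the size rule were higher once the median shift and the length trend were both taken out. Of 297 protein-coding genes past the rule, 95 were left with the median shift alone taken out and 94 with both. An effect of GBC stays open and untested.

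The 10 splits of the 6 Re-table libraries into groups of 3 are too few for a share under 0.05. The real split called 0 genes and the highest other split 5. At an unadjusted p under 0.05 the real split gave 745 genes and the highest other 1003, which sets DMSO replicate 1 with Re replicates 1 and 2. For gene lists the real split called 3 and the highest other 4.

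Lars2, a mitochondrial leucyl-tRNA synthetase gene, was at 54.99, 3780 and 2037 TPM in DMSO replicates 1, 2 and 3 of the Re table and at 73.3, 29.7 and 52.8 TPM in the Re libraries. The mitochondrial rRNA mt-Rnr1 was at 21658, 40910 and 37763 TPM in the same DMSO libraries and at 16289, 17246 and 32999 TPM in the Re libraries. DMSO replicate 2 stood apart on the first principal component, which held 30.4% of the variance.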
